A study of Homo sapiens with 8 samples.

How the data were processed

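RNA was measured in 8 libraries from LS174T cells, an established human colon adenocarcinoma line. The cells were derivatives carrying an inducible short hairpin RNA against ASCL2, a transcription factor of intestinal stem cells, or against WiNTRLINC1, a long non-coding RNA. The 4 groups were named by the sample titles: untreated and doxycycline-treated cells of the ASCL2 line, and untreated and doxycycline-treated cells of the WiNTRLINC1 line, with 2 libraries each. Per the labels' protocols, treated cells grew for 3 days in doxycycline at 1 ug/ml, control cells grew for 3 days without it, RNA was isolated with Trizol, mRNA was fragmented with RNase III, and libraries were sequenced on the Ion Proton. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The genotype label of all 8 samples names the other target than the title and source name do. The groups follow the titles, and the targeted gene ASCL2 is reported first in every library. Because ASCL2 was lower with doxycycline in both lines, it does not settle which of the labels is right.

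Per the submitters' processing notes, cutadapt, TopHat2 2.0.9, Cufflinks and DESeq were used, and the builds hg19, GRCh37 and mm9 are named without a role. The counting program and its use of strand are not given in the sources used here. The deposited score of a gene is a whole number, and the values themselves show that it is a scaled read count, not a raw one. In 7 of the 8 libraries some low whole numbers never occur or occur far more often than their neighbours, as happens when counts are multiplied by a factor per library and rounded. In the first untreated library of the ASCL2 line, 64 whole numbers under 400 that its factor cannot give were used by 0 of the 22159 genes in that range. In the first untreated library of the WiNTRLINC1 line, 14 of 24180 genes lay at the 40 such numbers. The factors estimated from these gaps and pile-ups ran from 0.7979 to 1.1912, and none was found in the second doxycycline library of the ASCL2 line. Deposited totals lay between 21524463 and 22941231 per library, and dividing by the factors gave an estimated 18.6 M to 28.0 M reads. Between 31503 and 33959 genes per library had a value above 0. Precision at the level of a gene is set by these depths and by the 2 libraries per group. Replicate pairs differed by more than counting noise, with a chi-square per degree of freedom between 5.13 and 7.06, so no pair was treated as a repeat of 1 library.

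Each file listed 57736 Ensembl gene identifiers, of which 39501 matched a symbol in the gene name table, and the rest held 2.34% of the summed values. GENCODE version 29 served for gene type, chromosome, transcript length and GC content, and no coordinates are printed because its build is not the one named by the submitters. WiNTRLINC1 matched no identifier in the reference tables and is not analysed here, and neither are the mitochondrially encoded transcripts.

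The test fixed for read counts was not applicable to scaled values, so the fallback fixed with it was used: limma 3.58.1 in R 4.3.3 on log2(value + 1), with a mean-variance trend, over all 8 libraries and 4 groups without covariates. Fold changes are therefore on the log2(value + 1) scale, which understates changes of genes with low values. Genes with a value of at least 10 in at least 2 libraries were tested, which left 22100. The fit had 4 residual and 10.5 prior degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were doxycycline against untreated cells in each line, the difference of these 2 responses (WiNTRLINC1 line minus ASCL2 line), and the untreated WiNTRLINC1 line against the untreated ASCL2 line. The libraries hold no doxycycline-treated cells without a hairpin, so doxycycline and hairpin cannot be told apart within a line. The 2 knockdown comparisons use different control libraries. Genes called in both were compared with n1 × n2 / N and a one-sided Fisher exact test, and log2 fold changes were correlated across genes, which are not independent replicates.

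There were 22 gene lists, tested with camera from limma at a preset inter-gene correlation of 0.01 with Benjamini-Hochberg adjustment over the 18 lists with at least 5 tested members and 3 comparisons (54 tests). The lists were also tested with an estimated correlation and with fry. These are not among the 20 settings over which single lists are followed below, which are alternatives with camera at the preset correlation. For the untreated lines the adjustment was over the 18 lists. The named genes followed a rule: ASCL2; per knockdown the 10 genes per direction with the largest change among called genes with a symbol, a mean log2 CPM of at least 2 and both treated libraries beyond both untreated ones; up to 4 members per list with the smallest adjusted p in a comparison; the 10 genes per direction with the largest smaller change among those called in both; and the 5 genes per direction with the largest differences between responses and between untreated lines. A few genes that this rule names are not reported here. Groups, comparisons, tests, lists, this rule and most of the alternative settings were fixed before the data were examined.

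The alternatives were median-ratio and upper-quartile scaling, no filter, a filter of 1 CPM in every library of a group, the replicate number as a block over both lines or within each, each line fitted alone, each library left out in turn, and a 2-fold minimum. Pseudocounts of 0.5 and 5, no mean-variance trend, voom from limma on the estimated reads, and lists without ASCL2 were added after the data were seen. The fit was tested on 10 simulated data sets with 200 changed genes per knockdown comparison, scaled and rounded like the real libraries. Of genes changed 2-fold it recovered 65% in the ASCL2 comparison and 64.4% in the WiNTRLINC1 comparison, each run on 22260 genes on average, and at 4-fold 84.1% and 87.4%. At 1.5-fold the shares were 49.9% and 46.1%. Among the simulated calls, 5.5% in the ASCL2 comparison and 7.8% in the WiNTRLINC1 comparison were false, both above the nominal share. The number of simulations was raised from 1 to 10 after the first also lay above it, and all 10 are pooled here. The real comparisons called 5884 and 4104 genes, far more than the 200 changed in simulation. Because the adjusted threshold depends on the share of genes changed, the simulated shares are not estimates for the real calls. Simulated genes of like mean value were also given the same variability between libraries, which real genes need not share. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.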

Results

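Gene expression was measured by RNA sequencing in LS174T colon cancer cells that express, on addition of doxycycline, a hairpin against ASCL2 or against the long non-coding RNA WiNTRLINC1. The study compared knockdown with control cells to find the genes that change on loss of either transcript. Each of the 4 groups, untreated and doxycycline-treated cells of each line, held 2 libraries. Deposited totals were close, from 21524463 to 22941231 per library, because the values had been scaled before deposit. The first principal component of the log2 values held 73.3% of the variance and separated the lines, and the second held 9.1% and separated treated from untreated libraries.

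ASCL2 (ENSG00000183734, chromosome 11) was lower in all 4 doxycycline-treated libraries than in any untreated library. In the ASCL2 line the deposited value was 2855 and 3373 in the untreated libraries and 532 and 586 in the treated ones. In the WiNTRLINC1 line it was 2540 and 2034 untreated and 805 and 697 treated. The fall was 5.55-fold in the ASCL2 line (log2 fold change -2.47 ± 0.117 SE, n = 2 per group, limma with Benjamini-Hochberg adjusted p = 3.93e-09) and 3.03-fold in the WiNTRLINC1 line (-1.60 ± 0.117, limma with Benjamini-Hochberg adjusted p = 3.46e-07). The responses differed by 0.87 ± 0.165 on the log2 scale (limma with Benjamini-Hochberg adjusted p = 0.00206), so the fall was smaller in the WiNTRLINC1 line.

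**Figure D1:**
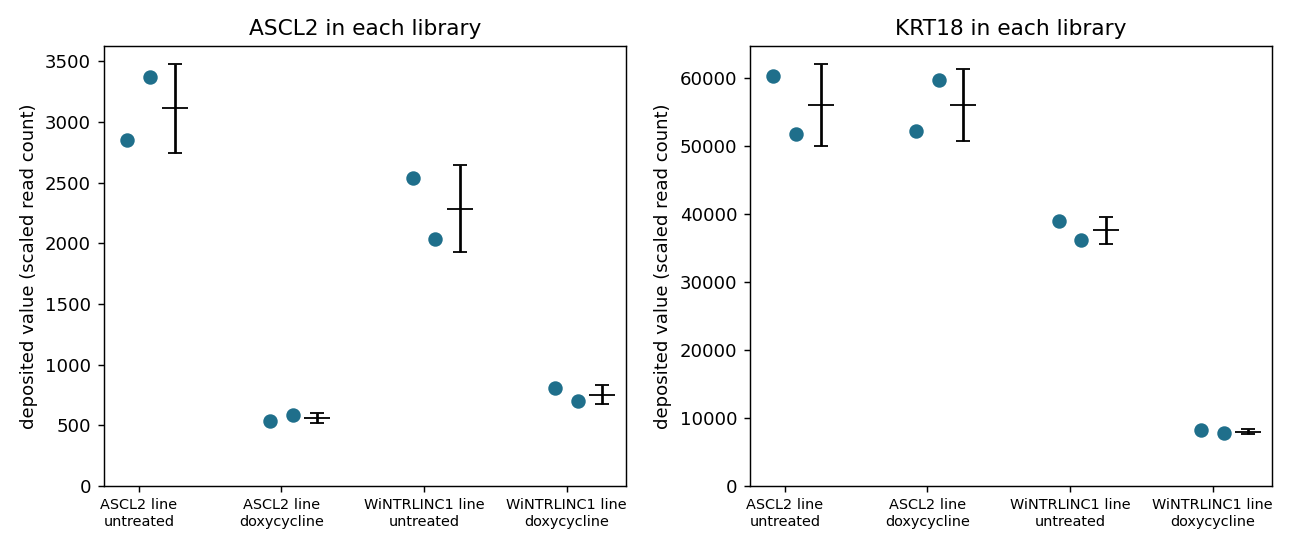
Deposited values (scaled read counts, linear axis from 0) of ASCL2 and KRT18 in each of the 8 libraries; points are libraries, and the bar beside them is the group mean with its SD (n = 2). ASCL2 lies between 532 and 805 in the 4 treated libraries, and KRT18 is lowest in the 2 treated libraries of the WiNTRLINC1 line.

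The comparison within the ASCL2 line asked which genes changed when ASCL2 was knocked down. Among the largest falls were SMOC2, a matrix protein and intestinal stem cell marker, from 975 ± 31.1 to 136 ± 1.41 (mean ± SD, n = 2; 7.12-fold), and PHGR1, a small protein of the gut epithelium, 9.02-fold. BGN, the matrix proteoglycan biglycan, fell 7.19-fold, IGFBP3, a binding protein of insulin-like growth factors, 6.85-fold, and PCK1, a gluconeogenesis enzyme, 6.65-fold. The adhesion receptor ADGRB1 fell 7.42-fold, the sterol transfer protein gene GRAMD1B 7.37-fold, the bHLH factor ATOH8 5.70-fold and the MHC class II chaperone CD74 5.63-fold. TEX19 rose 12.4-fold, from 115 ± 1.41 to 1438 ± 14.1, and the chemokine CXCL1 rose 6.32-fold. The chromatin protein HMGA2 rose 5.57-fold, the EGF receptor ligand EREG 4.78-fold, the immediate early gene EGR1 4.2-fold and the ERK phosphatase DUSP5 3.94-fold. CCR2 rose 4.84-fold, DHRS2 4.82-fold, LINC00520 4.73-fold and the kallikrein KLK7 3.96-fold. PNMA6E showed the largest fall of the genes named by the rule, from 1845.5 ± 136 to 36 ± 4.24 or 50.0-fold, and is uncertain because close copies in its gene family can share reads. The adjusted p of these 20 genes from limma with Benjamini-Hochberg adjustment ran from 5.55e-13 for PNMA6E to 1.44e-06 for EGR1.

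In the cell cycle list 25 of 27 members fell in the ASCL2 line, 0 rose and 2 did not pass the test, and the count adjusted over the list alone was also 25. The replication helicase subunit MCM3 fell by 1.25 on the log2 scale, thymidylate synthase TYMS by 1.23, the transcription factor E2F1 by 1.10 and the mitotic regulator CDC20 by 0.75. Camera called the list with a Benjamini-Hochberg adjusted p = 6.96e-15, and adjusted p = 0.0258 with an estimated correlation. Among intestinal stem cell genes 11 of 20 fell, 4 rose and 5 did not pass, with the same numbers adjusted over the list alone. The receptor EPHB3 fell by 1.44 on the log2 scale and the ion transporter SLC12A2 by 0.98, beside SMOC2 and ASCL2 itself (camera, Benjamini-Hochberg adjusted p = 0.000156; adjusted p = 0.152 with an estimated correlation). Of the Wnt targets, 12 of 25 fell, 5 rose and 8 did not pass, with the same numbers adjusted over the list alone. Among them the cyclin CCND1 rose by 1.4 on the log2 scale while EPHB3 and SLC12A2 fell (camera, Benjamini-Hochberg adjusted p = 0.018; adjusted p = 0.473 with an estimated correlation). Wnt and stem cell lists share members, and both hold the targeted gene. Without ASCL2 the Wnt list was no longer called (camera, Benjamini-Hochberg adjusted p = 0.069, the highest of 20 settings, with the lowest at 0.0082), while the stem cell list was (adjusted p = 0.0012).

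In the cholesterol synthesis list 15 of 25 members rose in the ASCL2 line, 2 fell and 8 did not pass, with the same numbers adjusted over the list alone. HMGCS1, which makes HMG-CoA, rose by 1.57 on the log2 scale, the sterol oxidase MSMO1 by 1.33 and squalene epoxidase SQLE by 1.09 (camera, Benjamini-Hochberg adjusted p = 1.68e-06; adjusted p = 0.0767 with an estimated correlation). Goblet cell genes included 9 of 20 that fell, 1 that rose and 10 that did not pass, with 10 falling and 1 rising adjusted over the list alone. ATOH1, the secretory lineage factor, had 27 and 20 untreated and 3 and 0 treated. The glycosyltransferase ST6GALNAC1 fell by 0.77 on the log2 scale, the trefoil peptide TFF2 by 0.66 and the mucin MUC5B by 0.65 (camera, Benjamini-Hochberg adjusted p = 0.005; adjusted p = 0.488 with an estimated correlation). Of the hypoxia and glycolysis genes 9 of 24 rose, 1 fell and 14 did not pass, with 12 rising and 2 falling adjusted over the list alone. They included NDRG1 at 1.15, the carbonic anhydrase CA12 at 0.90 and the glucose transporter SLC2A1 at 0.75 (camera, Benjamini-Hochberg adjusted p = 0.00442; adjusted p = 0.585 with an estimated correlation). Among cytosolic ribosomal proteins 15 of 33 fell, 2 rose and 16 did not pass, with 17 falling and 2 rising adjusted over the list alone. RPS4X fell by 0.91 and RPL3 by 0.60 on the log2 scale (camera, Benjamini-Hochberg adjusted p = 0.00552; adjusted p = 0.884 with an estimated correlation), and the list was not called without the first treated library (camera, adjusted p = 0.326, against 2.49e-06 at the lowest of 20 settings).

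Over all 22100 genes tested in the ASCL2 line, limma with Benjamini-Hochberg adjustment called 5884, of which 3075 rose and 2809 fell. At least 2-fold changes were seen in 978 of them, 368 up and 610 down. The count was 3665 without the second treated library of this line and 3410 without the mean-variance trend.

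The comparison within the WiNTRLINC1 line asked which genes changed when WiNTRLINC1 was targeted. KRT18, the type I keratin of simple epithelia, fell 4.72-fold, from 37582.5 ± 1970 to 7965.5 ± 327 (mean ± SD, n = 2). In the ASCL2 line its log2 fold change was 0.00 ± 0.090 SE, and the difference of -2.24 ± 0.127 passed limma with Benjamini-Hochberg adjusted p = 1.13e-07. The Notch ligand DLL4 fell 5.13-fold, from 363 ± 1.41 to 70 ± 5.66, and the endocytic adaptor EPN1 fell 4.50-fold. PNMA6E fell 5.6-fold. Another 6 of the 10 largest falls named by the rule were KRT18 pseudogenes (KRT18P25, KRT18P13, KRT18P10, KRT18P34, KRT18P16 and KRT18P12), between 4.43-fold and 5.14-fold. They are uncertain because copies of a gene can share its reads. The calcium-binding protein CALB2 rose 5.18-fold, from 70 ± 8.49 to 365.5 ± 10.6, the calcium channel CACNA1H rose 4.22-fold, and the myosin light chain MYL9 and the membrane protein EMP1 each rose 4.13-fold. ARAP3 rose 4.05-fold, PMP22 3.94-fold, AGPAT4 3.72-fold, the forkhead factor FOXQ1 3.56-fold and SYNE3 3.51-fold. The adjusted p of these 19 genes from limma with Benjamini-Hochberg adjustment ran from 6.17e-09 for KRT18 to 2.32e-05 for KRT18P34.

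In the cholesterol synthesis list 21 of 25 members rose in the WiNTRLINC1 line, 0 fell and 4 did not pass, with 21 rising and 1 falling adjusted over the list alone. SQLE rose by 1.60 on the log2 scale and MVD by 0.90. Camera gave a Benjamini-Hochberg adjusted p = 4.03e-16, and adjusted p = 0.0258 with an estimated correlation. Of the Wnt targets 12 of 25 fell, 3 rose and 10 did not pass, with 13 falling and 3 rising adjusted over the list alone. The Wnt-responsive transcription factor TCF7 fell by 1.29 on the log2 scale, NKD1 by 0.86 and SLC12A2 by 0.71 (camera, Benjamini-Hochberg adjusted p = 1.26e-05, and 0.000108 without ASCL2; adjusted p = 0.152 with an estimated correlation). Among stem cell genes 10 of 20 fell, 0 rose and 10 did not pass, with the same numbers adjusted over the list alone. SMOC2 fell by 1.58 and the BMP co-receptor RGMB by 1.01 (camera, Benjamini-Hochberg adjusted p = 5.5e-06, and 5.31e-05 without ASCL2; adjusted p = 0.112 with an estimated correlation).

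Cell cycle genes in the WiNTRLINC1 line comprised 10 of 27 that fell, 1 that rose and 16 that did not pass, with 13 falling and 1 rising adjusted over the list alone. E2F1 fell by 0.86, FOXM1 by 0.52 and CDC20 by 0.45 on the log2 scale (camera, Benjamini-Hochberg adjusted p = 0.000132; adjusted p = 0.0916 with an estimated correlation). Interferon response genes included 10 of 24 that fell, 0 that rose and 14 that did not pass, with 10 falling adjusted over the list alone. The regulator IRF7 fell by 1.26, IFIT3 by 0.81 and the RNA sensor RIGI by 0.49 (camera, Benjamini-Hochberg adjusted p = 0.000227; adjusted p = 0.585 with an estimated correlation). Of the YAP targets 6 of 14 rose, 1 fell and 7 did not pass, with the same numbers adjusted over the list alone. TGFB2 rose by 2.40 on the log2 scale, ANXA1 by 1.01 and CRIM1 by 0.98, while NUAK2 fell by 0.91 (camera, Benjamini-Hochberg adjusted p = 0.0187; adjusted p = 0.473 with an estimated correlation). That call was lost without the second untreated library of this line (camera, Benjamini-Hochberg adjusted p = 0.0606) and when the line was fitted alone (adjusted p = 0.0559), with the lowest of 20 settings at 0.00641. Only 3 of 33 ribosomal protein genes fell, 0 rose and 30 did not pass, with 3 falling adjusted over the list alone, among them RPL10A by 0.46 on the log2 scale (camera, Benjamini-Hochberg adjusted p = 0.011; adjusted p = 0.887 with an estimated correlation). Without the first treated library of this line the ribosomal list was not called (camera, Benjamini-Hochberg adjusted p = 0.088, against 0.00224 at the lowest of 20 settings).

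Over all genes tested in the WiNTRLINC1 line, limma with Benjamini-Hochberg adjustment called 4104, of which 2108 rose and 1996 fell, and 596 changed at least 2-fold, 237 up and 359 down. The count was 2709 without the first untreated library of this line, 2706 and 2398 without the first and second treated library, 2395 without the filter and 1873 without the mean-variance trend.

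**Figure D2:**
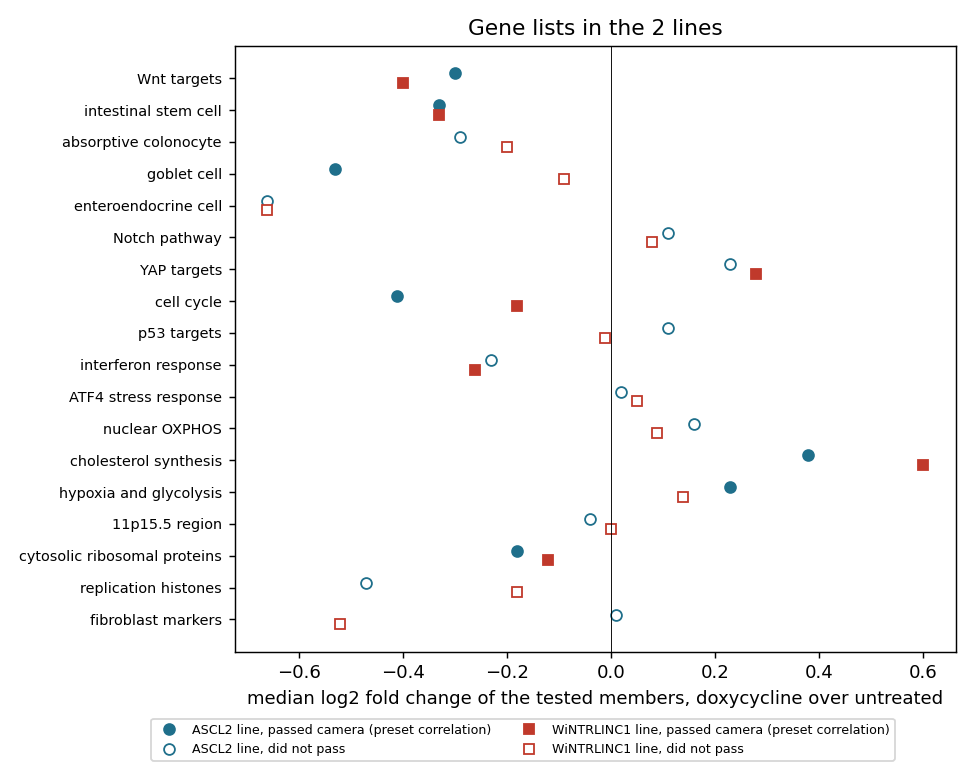
Median log2 fold change of the tested members of each gene list with at least 5 tested members, doxycycline over untreated, in the ASCL2 line (circles) and the WiNTRLINC1 line (squares); filled symbols passed camera with the preset correlation. Cholesterol synthesis lies at 0.38 and 0.60 and cell cycle at -0.41 and -0.18.

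The remaining list results did not pass camera with Benjamini-Hochberg adjustment or had too few members for it. Among p53 targets 8 of 24 rose and 4 fell in the ASCL2 line, where the death receptor TNFRSF10B and FAS each rose by 1.17 and the cell cycle inhibitor CDKN1A by 0.97 on the log2 scale, and 6 rose and 5 fell in the WiNTRLINC1 line. Of the absorptive colonocyte genes, 4 of 17 rose and 5 fell in the ASCL2 line, with ALPI at 2.13, DPP4 at 1.37 and PHGR1 at -3.17. In the WiNTRLINC1 line 5 rose, among them CEACAM6 at 1.13, and 2 fell. There the list's median was -0.20 while its mean was 0.04 and camera's direction was up. Goblet cell genes in the WiNTRLINC1 line included 5 of 20 that rose, with TFF1 at 1.08 and MUC5AC at 1.03, and 2 that fell. Among the falls was ATOH1 at -2.44, with 58 and 74 untreated and 9 and 14 treated. The median of the goblet cell list, -0.09, was opposite to camera's direction. Of 12 Notch pathway genes, 4 rose and 4 fell in the ASCL2 line and 3 rose and 4 fell in the WiNTRLINC1 line, where the median of 0.08 and the mean of -0.13 differed in sign. LFNG fell in both, by 1.34 and 0.95. YAP targets in the ASCL2 line had 7 rising and 2 falling, hypoxia and glycolysis genes in the WiNTRLINC1 line 6 rising and 3 falling, and interferon response genes in the ASCL2 line 4 rising and 7 falling. ATF4 stress response genes showed 5 of 25 rising and 3 falling in the ASCL2 line and 3 each in the WiNTRLINC1 line. Nuclear OXPHOS genes showed 10 of 27 rising and 5 falling in the ASCL2 line and 5 each in the WiNTRLINC1 line. In the 11p15.5 region, where ASCL2 lies, 7 of 25 genes rose and 4 fell in the ASCL2 line and 4 rose and 3 fell in the WiNTRLINC1 line. ASCL2 itself was counted among the falls in both lines. Of 8 replication histones 2 fell in the ASCL2 line, and in the WiNTRLINC1 line limma called 0, with 0 at an unadjusted p under 0.05. Of 7 enteroendocrine genes limma called 0 in either line, with 3 in the ASCL2 line and 2 in the WiNTRLINC1 line at an unadjusted p under 0.05 and medians of -0.66 in both. The Paneth, fibroblast, immune and endothelial marker lists had 4, 5, 4 and 3 tested members, of which limma called 1, 1, 0 and 1 as lower in the ASCL2 line and 0 in the WiNTRLINC1 line, where 0, 1, 1 and 1 had an unadjusted p under 0.05. Median, mean and camera direction also differed in sign for Notch pathway and fibroblast genes in the ASCL2 line and for p53 target and fibroblast genes in the WiNTRLINC1 line.

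The series title names a regulatory loop between both targets, which raises the question of which genes responded in both lines. HMGA2 rose 5.57-fold and 2.81-fold in the ASCL2 and WiNTRLINC1 lines, CALB2 3.87-fold and 5.18-fold, and the AP-1 subunit FOSL1 3.01-fold and 2.56-fold. MYCN rose 2.27-fold and 2.69-fold, PMP22 2.18-fold and 3.94-fold, AGPAT4 2.20-fold and 3.72-fold, NKIRAS1 2.49-fold and 2.22-fold and APC2 2.48-fold and 2.30-fold. HHLA3-AS1 rose 2.70-fold and 2.50-fold, but it is antisense to another gene and the counting's use of strand is not given. Its call in the WiNTRLINC1 line was lost without the filter and without the mean-variance trend (limma, Benjamini-Hochberg adjusted p = 0.0582 and 0.065). SMOC2 fell 7.12-fold and 2.99-fold, BGN 7.19-fold and 3.0-fold, CD74 5.63-fold and 2.92-fold, ADGRB1 7.42-fold and 2.62-fold and EPN1 2.52-fold and 4.50-fold, beside ASCL2 and PNMA6E. SLC24A1 fell 3.35-fold and 2.72-fold. The metallothionein MT2A fell 3.04-fold and 2.81-fold and the steroid-conjugating enzyme UGT2B17 5.49-fold and 2.49-fold, both uncertain because they belong to families of similar genes. The largest adjusted p among these 19 genes from limma with Benjamini-Hochberg adjustment was 0.00198, for HHLA3-AS1 in the WiNTRLINC1 line.

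In all, 926 genes rose in both lines where independent lists would share 293.3 (one-sided Fisher exact test, p = 1.57e-283), and 651 fell in both against 253.7 (p = 1.26e-133). Another 240 rose in the ASCL2 line and fell in the WiNTRLINC1 line, against 277.7, and 188 did the opposite, against 267.9. Of the 2005 genes called in both, 1577 or 78.7% changed in the same direction. Across all 22100 genes the log2 fold changes had a Pearson r of 0.2 and a Spearman rho of 0.229, and across the 8438 genes with a mean value of at least 500 these were 0.321 and 0.330. Genes are not independent replicates, so these values describe the tables. The expected numbers also take every gene as equally likely to be called. Detection rose with the value in simulation, so part of the excess may come from genes that are easier to call in both lines, which was not tested. The number called in the same direction was 935 without the second treated library of the WiNTRLINC1 line, 822 without the filter and 570 without the mean-variance trend.

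**Figure D3:**
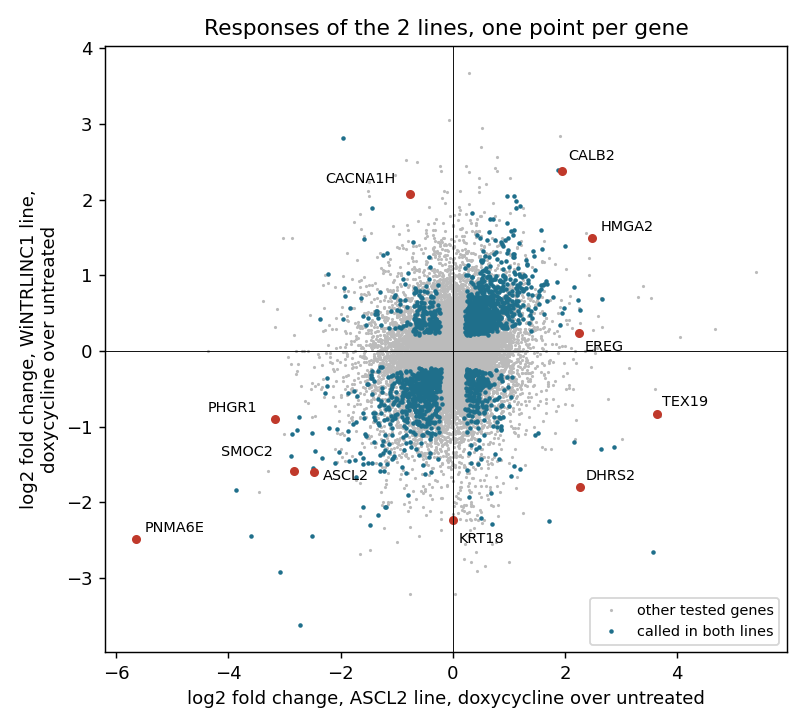
Log2 fold change, doxycycline over untreated, in the ASCL2 line (x axis) and the WiNTRLINC1 line (y axis), one point per tested gene; larger blue points are the 2005 genes called in both lines, and red points are named genes. ASCL2, SMOC2 and PNMA6E lie low on both axes, and TEX19 and DHRS2 lie on opposite sides of 0.

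The test of the difference asked which genes responded differently in the lines. TEX19 rose 12.4-fold in the ASCL2 line and fell 1.77-fold in the WiNTRLINC1 line, and DHRS2 rose 4.82-fold and fell 3.47-fold. ASB4 rose 2.06-fold and fell 3.14-fold. In the other direction CACNA1H fell 1.70-fold in the ASCL2 line and rose 4.22-fold in the WiNTRLINC1 line, NBDY fell 5.18-fold and rose 1.34-fold, and GRAMD1B fell 7.37-fold in the ASCL2 line against a log2 fold change of -0.17 ± 0.113 SE in the WiNTRLINC1 line that did not pass. Among called genes with a symbol and a mean log2 CPM of at least 2, PNMA6E and the pseudogenes AKR1B1P7, KRT18P13 and KRT18P16 complete the 5 largest differences in each direction. PNMA6E and these pseudogenes are uncertain because similar sequences can share reads, which was not tested. Cell cycle genes responded less negatively in the WiNTRLINC1 line, with 7 of 27 differing upward and 0 downward, or 10 upward adjusted over the list alone. MCM3 differed by 1.05, TYMS by 1.13 and the survivin gene BIRC5 by 1.12 on the log2 scale (camera, Benjamini-Hochberg adjusted p = 7.31e-06; adjusted p = 0.0767 with an estimated correlation). Goblet cell genes differed upward in 8 of 20 and downward in 0, or 10 and 1 adjusted over the list alone, with TFF2 at 1.44, the gastric-type mucin MUC5AC at 1.28 and TFF1 at 1.18 (camera, Benjamini-Hochberg adjusted p = 0.000917; adjusted p = 0.45 with an estimated correlation). Cholesterol synthesis genes differed upward in 11 of 25 and downward in 4, or 13 and 5 adjusted over the list alone, with HMGCS1 at -0.75 and MSMO1 at -1.59 among those downward (camera, Benjamini-Hochberg adjusted p = 0.0114; adjusted p = 0.243 with an estimated correlation). No shift in 1 direction was called for the Wnt target and stem cell lists (camera, Benjamini-Hochberg adjusted p = 0.546 and 0.432), but their members differed both ways. Of 25 Wnt targets 5 differed upward and 8 downward, and of 20 stem cell genes 6 differed upward and 4 downward. Over all genes, limma with Benjamini-Hochberg adjustment called 3314 differences, 1634 higher and 1680 lower in the WiNTRLINC1 line, against 1914 without the filter and 1313 without the mean-variance trend.

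The untreated cells of the lines were compared to see how far apart they started. PIGR, which carries immunoglobulins across epithelia, was 503-fold higher in the untreated WiNTRLINC1 line, at 33899.5 ± 14.8 against 67 ± 12.7 (mean ± SD, n = 2). The kallikrein KLK6 was 103-fold higher, TPM2, a tropomyosin, 53.1-fold, BGN 36.0-fold and VAV3 35.0-fold. The actin-bundling protein ESPN was 219-fold lower, at 12.5 ± 0.707 against 2957 ± 256, the collagen COL6A2 205-fold, the calcium-binding protein CALB1 169-fold, the growth factor TGFB1 123-fold and PXDN 91.6-fold. The largest adjusted p of these 10 genes from limma with Benjamini-Hochberg adjustment was 1.14e-09, for VAV3. In the interferon response list 19 of 24 genes were lower and 2 higher (camera, Benjamini-Hochberg adjusted p = 8.66e-06; adjusted p = 0.326 with an estimated correlation). Cholesterol synthesis genes were lower in 18 of 25 and higher in 0 (camera, Benjamini-Hochberg adjusted p = 1.79e-05; adjusted p = 0.0883 with an estimated correlation), and 6 of 8 replication histones were lower (camera, Benjamini-Hochberg adjusted p = 0.00792; adjusted p = 0.257 with an estimated correlation). Cell cycle genes were higher in 18 of 27 and lower in 1 (camera, Benjamini-Hochberg adjusted p = 0.000224; adjusted p = 0.0883 with an estimated correlation), stem cell genes higher in 12 of 20 and lower in 5 (camera, Benjamini-Hochberg adjusted p = 0.0105; adjusted p = 0.257 with an estimated correlation), and hypoxia and glycolysis genes higher in 14 of 24 and lower in 4 (camera, Benjamini-Hochberg adjusted p = 0.0445; adjusted p = 0.581 with an estimated correlation). Over all genes, limma with Benjamini-Hochberg adjustment called 12203 of 22100, or 55.2%, of which 5678 were higher and 6525 lower, and 5189 differed at least 2-fold. Under upper-quartile scaling the median log2 difference of all genes in this comparison moved by 0.138. Relative to it the cell cycle list lay at 0.36 and the cholesterol synthesis list at -0.32, with or without that scaling. A factor per library moves a list and all genes nearly alike, so these distances could hardly change and do not test the scaling.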

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

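The results below stand out because the response to doxycycline differed between the ASCL2 and WiNTRLINC1 lines by the test of the difference, and only the correlation and counts of pseudogenes with their parents were chosen after the result was seen. The differences are in log2 fold change, WiNTRLINC1 line minus ASCL2 line, and each passed limma with Benjamini-Hochberg adjustment. Above 0 they were 3.16 for PNMA6E, 2.85 for CACNA1H, 2.80 for NBDY, 2.78 for AKR1B1P7, 2.71 for GRAMD1B, 2.27 for PHGR1, 2.21 for ARAP3, 1.86 for PCK1, 1.73 for IGFBP3, 1.58 for SYNE3, 1.5 for ADGRB1, 1.49 for FOXQ1, 1.43 for ATOH8, 1.26 for BGN, 1.25 for SMOC2, 1.14 for UGT2B17, 1.08 for MYL9, 0.96 for EMP1, 0.95 for CD74, 0.87 for ASCL2, 0.86 for PMP22 and 0.76 for AGPAT4. Below 0 they were -4.46 for TEX19, -4.07 for DHRS2, -2.69 for ASB4, -2.56 for EGR1, -2.16 for DLL4, -2.14 for KLK7, -2.01 for EREG, -1.97 for CXCL1, -1.74 for CCR2, -1.56 for LINC00520, -1.41 for DUSP5, -0.99 for HMGA2 and -0.84 for EPN1. In the KRT18 family they were -2.98 for KRT18P13, -2.71 for KRT18P16, -2.67 for KRT18P25, -2.62 for KRT18P34, -2.47 for KRT18P10, -2.24 for KRT18 and -2.15 for KRT18P12. Among the lists, camera with Benjamini-Hochberg adjustment called the difference for cell cycle genes (adjusted p = 7.31e-06), goblet cell genes (adjusted p = 0.000917) and cholesterol synthesis genes (adjusted p = 0.0114). None of these 3 list calls held with an estimated correlation (adjusted p = 0.0767, 0.45 and 0.243).

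Many pseudogenes changed together with the gene they were copied from. In the WiNTRLINC1 line 48 of 55 tested KRT18 pseudogenes fell with KRT18 and 0 rose, and in the ASCL2 line 0 fell and 2 rose. Across 1655 processed pseudogenes with a mean value of at least 50 and a tested parent, the log2 fold changes of pseudogene and parent had a Pearson r of 0.87 in the WiNTRLINC1 line and 0.85 in the ASCL2 line (across genes, which are not independent replicates). Of all 2967 pseudogenes with a tested parent, including those with lower values, limma with Benjamini-Hochberg adjustment called 257 in the WiNTRLINC1 line, which were 6.3% of the calls there, and 427 in the ASCL2 line, which were 7.3%. Neither reads of the parent counted on its copies nor regulation of the pseudogenes themselves was tested, and both stay open.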

How the results depend on the processing

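Pseudocounts, the fit without a trend, voom, the lists without ASCL2, the lists of the untreated lines under each scaling and the simulated changes by value were chosen after the data were seen, and the other alternatives before. No result reversed. Median-ratio and upper-quartile scaling, the stricter filter, the pseudocounts and voom kept all counts of genes and lists within 1.5 times, as did each line fitted alone for the counts it gives (the changes in each line and in both), and the median of all genes moved by less than 0.1 in each comparison but that of the untreated lines, where upper-quartile scaling moved it by 0.138. The lists called there were called in the same direction under both scalings, and upper-quartile scaling also called absorptive colonocyte genes and p53 targets (camera, Benjamini-Hochberg adjusted p = 0.0377 and 0.0428). Without the filter the counts fell to 2395 (WiNTRLINC1 line), 1914 (difference) and 822 (same direction in both), with 43363 genes tested. Without the trend they were 3410 (ASCL2 line), 1873 (WiNTRLINC1 line), 1313 (difference) and 570 (same direction in both). The cause was not tested for either. A 2-fold minimum left 978, 596, 919 and 5189 in the ASCL2 line, WiNTRLINC1 line, difference and untreated lines. Leaving out each library in turn, where the lone library is assumed to vary like the other groups, gave 3665 to 5862 genes in the ASCL2 line, lowest without its second treated library. It gave 2398 to 4131 in the WiNTRLINC1 line, with 2398, 2706 and 2709 without the second treated, first treated and first untreated library. The difference ranged from 2315 to 2891, the untreated lines from 10458 to 12002, same direction in both from 935 (without the second treated WiNTRLINC1 library) to 1309, and lists called from 17 to 19. The log2 fold change of ASCL2 ranged from -2.59 to -2.35 and from -1.76 to -1.44. Of the 17 list calls, 2 held with an estimated correlation, and without ASCL2 camera called 16. The fry test, which does not compare a list with other genes, called 22 but did not hold all of the 17. It lost the interferon list in the WiNTRLINC1 line (fry, Benjamini-Hochberg adjusted p = 0.0756). It also lost the ribosomal protein list in the ASCL2 and WiNTRLINC1 lines (fry, Benjamini-Hochberg adjusted p = 0.164 and 0.316). With the replicate block over both lines the counts were 5962, 4182, 3403 and 12261, and within each line 6148, 4298, 3511 and 10740. Replicate numbers mark no stated pairing, and the replicate differences of treated and untreated cells correlated at -0.052 and 0.105. Single genes were followed over the settings only where the rule named them for a large change or difference, not as list members alone. Of their values 1612 stayed on their side of the threshold and 2 were lost, both for HHLA3-AS1 in the WiNTRLINC1 line. Because these genes were picked for large changes, this does not measure how stable other calls are. The planned DESeq2-type Wald alternative was not run, because the values are not counts. Low values limited detection in simulation, where 1.5-fold changes were found in 18.6% and 13.9% of genes with a mean value under 500, and in 96.2% and 93.9% of the others (ASCL2 and WiNTRLINC1 comparison).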

Other observations

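All tests in this part were chosen after the result was seen, except those of the ATF4 list, the interferon list, read depth and transcript length or GC content for genes shared by the lines. Gene groups outside the lists fixed beforehand were examined after the results were seen, on lists of textbook target genes from which every gene already named was left out. They were first run with those genes in, which gave a higher ERK median and met what was set for NRF2 targets. The ATF4 and SRF explanations below were first counted as excluded and then left open, because members of both lists went both ways. ERK output genes, which rise with growth factor signalling, rose in 9 of 16 and fell in 0 in the ASCL2 line, and rose in 11 and fell in 0 in the WiNTRLINC1 line. NRF2 target genes, which respond to oxidative stress, rose in 9 of 15 and fell in 2 in the ASCL2 line, and rose in 6 and fell in 2 in the WiNTRLINC1 line. SRF target genes of the actin cytoskeleton rose in 7 of 13 and fell in 0 in the ASCL2 line, and rose in 2 and fell in 3 in the WiNTRLINC1 line.

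A change of growth factor signalling may be involved in the rise of ERK output genes: their median log2 fold change in the ASCL2 line was 0.30 ± 0.18 SE (camera, Benjamini-Hochberg adjusted p = 8.88e-06; adjusted p = 0.182 with an estimated correlation). It was 0.45 in the WiNTRLINC1 line (camera, Benjamini-Hochberg adjusted p = 2.57e-06, and 0.182 with an estimated correlation). No shift of the list in 1 direction was called between the lines (camera, Benjamini-Hochberg adjusted p = 0.362), but 3 of 16 members differed upward and 5 downward. EGR1, EREG and DUSP5, left out because they were already named, responded lower in the WiNTRLINC1 line. The test therefore cannot show that ERK output genes responded alike. An actin and SRF signal in the WiNTRLINC1 line, a hypothesis raised by MYL9, was not borne out or excluded, with a median of -0.03 ± 0.11 SE over members that went both ways. In the ASCL2 line the SRF list was called upward at a median of 0.41 (camera, Benjamini-Hochberg adjusted p = 0.000484; adjusted p = 0.201 with an estimated correlation), and the lines differed (adjusted p = 0.00569; adjusted p = 0.24 with an estimated correlation). An oxidative stress response in both lines was left open as well, with a median of 0.10 over NRF2 targets in the WiNTRLINC1 line (camera, Benjamini-Hochberg adjusted p = 0.0542) and 0.39 in the ASCL2 line (adjusted p = 0.00214; adjusted p = 0.201 with an estimated correlation). The response of NRF2 targets was lower in the WiNTRLINC1 line by the test of the difference (camera, Benjamini-Hochberg adjusted p = 0.0386; adjusted p = 0.31 with an estimated correlation).

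The 1577 genes that changed in the same direction in both lines could come from the fall of ASCL2 in both, which the design names and which was not tested, or from doxycycline or the procedure. An interferon response to the hairpin is argued against by the WiNTRLINC1 line, where the median of the interferon list was -0.26 ± 0.08 SE with 0 of 24 members rising and 10 falling, while in the ASCL2 line 4 rose and 7 fell. The shared changes were not confined to low values. At a mean value of at least 500 the fold changes correlated at 0.321, against 0.2 over all genes. Low read depth is not tested by this, because counting noise in separate libraries would weaken such a correlation. Length or GC content is argued against by a correlation of 0.193 after their trends were removed over 97.1% of the genes. Doxycycline stays open: the ATF4 list that mitochondrial stress would raise had a median of 0.05 ± 0.07 SE in the WiNTRLINC1 line, low enough for the bound set beforehand, but that bound was ill chosen because members went both ways and such a median decides nothing. If doxycycline acted alike in both lines few of the shared genes should differ in size, and 16.3% (257) did, which with no treated cells lacking a hairpin cannot be told apart from an effect of the knockdowns.

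The untreated lines differed in 12203 genes. Scaling as the only cause is argued against by 5678 higher and 6525 lower calls, since a factor per library shifts all genes 1 way. The 12132 calls under median-ratio scaling add little to this. The deposited values were already scaled, with median ratios over all libraries between 0.979 and 1.035, so rescaling hardly changed them. The calls were not confined to low values, with 69.1% of genes called at a mean value of at least 500 and 55.2% over all. Low read depth is not tested by these shares, because detection rises with the value. Whole-chromosome copy number is argued against as the main cause, since chromosomes accounted for 0.56% of the variance of the log2 difference across 14627 genes, although their medians spread more (SD 0.07) than in any shuffle of the chromosomes (highest 0.058). Clonal origin and time in culture were not tested and stay open.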
